A study of Arabidopsis thaliana with 4 samples.

How the data were processed

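Leaf RNA of uninfested and infested Arabidopsis plants was measured on 4 one-colour Affymetrix ATH1 arrays, 2 per group, grouped by the sample titles. Per the series text, each replicate experiment held 10 uninfested and 10 infested plants in a growth chamber, 8 such experiments were done, and RNA of 2 experiments from each chamber was pooled into each array sample. The p-values thus measure the spread between pools.

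The deposited values are MAS 5.0 signal intensity on a linear scale, made by the authors with standard parameters per the labels and series text, with no version given in the sources used here. The trimmed mean signal, leaving out 2% of probe sets at each end, was 500.0 on each array, so each array had been scaled by the authors to the same mean. The authors' removal of genes called absent is not reflected in the table, and detection calls were not used here. No sequence of a genome was used, and no coordinates are given.

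The table held 22810 probe sets, of which 64 control probe sets were left out. Signals were taken as log2(signal + 16) with no further normalization, and probe sets whose mean was below the 40th percentile were not tested, which left 13648 and removed 9098. Fold changes are on this scale, which understates the change of dim genes. The dimmest tested probe set had a mean log2(signal + 16) equal to that of a signal of 116. The highest signal of 27 control probe sets for bacterial transcripts that were not added was 52.1. On a single array a tested probe set could still read below these controls, as AT3G13610 did with 9 on uninfested 2. In the tested set, 5 probe sets were at or below the array's highest such control on both uninfested arrays and 0 on both infested arrays.

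Probe sets were named through the platform annotation and updated by gene number to the RefSeq annotation of assembly TAIR10.1. In all, 13513 probe sets had 1 gene, 503 had several and 8730 are unnamed here; 13436 of the 13513 matched RefSeq and 77 did not. Of 348 loci in the gene lists fixed in advance, 47 had a probe set with 1 gene and 34 were tested. Most list members are thus unnamed here and were not analysed by name. Among them were all but PDF1.2 and THI2.1 of 18 defence and senescence genes chosen in advance. The 6003 unnamed probe sets that passed the filter were tested without a gene name. THI2.1 was too dim to test. Of 26 lists and the WRKY family, 7 had at least 3 tested genes and were tested; the lists with 0 tested genes were jasmonate signalling and response, callose synthases, oxidative stress, phenylpropanoids and lignin, flavonoids and anthocyanins, endoplasmic reticulum chaperones, heat shock, and the markers of phloem, xylem, trichomes, dividing cells, flowers and roots.

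Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, 2 residual degrees of freedom and 3.66 prior ones), with no block, and called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera on 1 probe set per gene, the brightest, over 7283 genes with an inter-gene correlation preset at 0.01, with an estimated correlation and fry beside it. Photosynthesis was the only fixed list called, with a fry p of 0.0173 before adjustment and of 0.000253 for change in either direction. With an estimated correlation 0 of the 7 lists held. That form of camera tests on the 2 residual degrees of freedom, so it had little power here to call any set. A set that fails it, here or below, is thus not shown to owe its call to correlated genes. With 2 arrays against 2, an exact permutation test of a single gene cannot reach a p under 0.05.

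The named genes were fixed by rule before the data were examined: the 12 largest rises and 12 largest falls among called probe sets with 1 gene, 18 defence and senescence genes, and the 4 tested members of each list with the smallest p. The test design, the lists and the alternatives were fixed, apart from those named as later, at the same time. Names outside this rule were chosen after their values were seen. These are RCA, the members of the groups made from annotation names, the genes that stood out on infested 2, rpl36, and the genes of the closing observations, which are said there to be so chosen. Such groups took every word of at least 6 letters, or symbol start of at least 3 letters, shared by at least 5 tested nuclear genes.

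The sample titles number the arrays 1 and 2 in each group, and the series text describes infested and control pools of the same experiments, so the number was taken to mark a shared experiment. The counts of calls with and without the block were already known when this was decided, and its basis is the series text. Across probe sets, the deviations of same-numbered arrays from their group means had a correlation of 0.264; probe sets are not independent replicates. The blocked fit had 1 residual degree of freedom and 7.26 prior ones, so its p-values rest mostly on variance borrowed across probe sets. It is given beside a result only where it changes the call or the count.

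The whole-array test was tested on simulated data for this comparison over 13648 probe sets: 6 of 100 changed by log2 1 and 81 of 100 changed by log2 2 were recovered, all in the right direction, with 3 false calls. Most 2-fold changes were thus missed in the simulation. It changed 200 probe sets and gave both groups the same spread, so the share missed in the real data may differ. Alternatives were other pseudocounts, quantile normalization, median scaling, other filters, no variance trend, robust variance, other thresholds, the replicate block, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.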

Results

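Transcript levels were measured in rosette leaves of Arabidopsis thaliana, accession Columbia, carrying nymphs of the silverleaf whitefly (Bemisia tabaci type B), an insect that feeds on phloem sap through its stylets. Plants were 21 days old when 100 adult whiteflies were released on each, the adults were taken off after 7 days, and rosettes were collected 28 days after infestation began, when the plants were 7 weeks old. Uninfested plants were grown alongside under 8 h of light per day. RNA was hybridized to 4 Affymetrix ATH1 arrays, 2 from infested and 2 from uninfested leaves, and each array carried RNA pooled from 2 replicate experiments, or 20 plants. The median signal was 189.2 and 193.8 on the uninfested arrays and 205.2 and 185.25 on the infested ones, after the authors' scaling of each array to a common trimmed mean. With 2 arrays per group, the number of arrays limits the precision of every value.

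The comparison asked which leaf transcripts differed between plants with developing nymphs and plants without. CHI (AT2G43570), a chitinase gene, rose from a mean signal of 438.2 ± 241 (SD, n = 2) in uninfested to 5589 ± 542 in infested leaves, 13.3-fold. AT3G13610, which encodes feruloyl-CoA hydroxylase of scopoletin synthesis, went from 36.6 ± 39.0 to 565.9 ± 77.4. The calmodulin-like gene CML41 rose 8.29-fold, from 221.7 ± 6.72 to 1957 ± 130, with an adjusted p of 0.0240 (limma with Benjamini-Hochberg adjustment). CHI, AT3G13610 and CML41 were among the 12 largest rises on log2(signal + 16) of called probe sets with 1 gene. Others of the 12 were the osmotin gene OSM34 (39.2 ± 34.1 to 462.6 ± 180) and UGT76B1 (50.6 ± 27.7 to 455.7 ± 158). The enzyme of UGT76B1 attaches glucose to salicylic acid and isoleucic acid. Also among them, the 2 berberine bridge enzyme-like oxidase genes AT1G26390 and AT1G26380 rose 7.92-fold and 7.15-fold. The other members of these 12 were AT2G44240 and, between 7.15-fold and 8.01-fold, AT3G18250, AT1G68620, AT3G28510 and SAL2. For AT3G13610, AT2G44240, OSM34 and UGT76B1, 1 of the 2 uninfested arrays read no higher than the brightest control for an absent bacterial transcript, so the pseudocount added to each signal sets much of their fold: that of AT3G13610 was 12.9 with 16, 22.1 with 1 and 6.49 with 64, and that of OSM34 was 9.29, 13.9 and 5.09.

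Genes that fell included LHCB4.3 (AT2G40100), which encodes a minor antenna protein of photosystem II, from 1932 ± 161 to 299.7 ± 37.7 (SD, n = 2), 6.18-fold lower in infested leaves. AT2G34620, of the mitochondrial transcription termination factor family, went from 2918 ± 3.89 to 416.7 ± 148, and AT5G22580 went from 5487 ± 311 to 796.5 ± 532. The beta-expansin gene EXPB1, whose product loosens cell walls, fell 5.42-fold, and AT2G14900, a gibberellin-regulated gene, went from 319.4 ± 32.6 to 44.8 ± 37.3. The remaining members of the 12 largest falls were AT5G22460, AT5G18460 and, between 4.60-fold and 6.81-fold, AT5G13140, AT5G12940, AT3G16670, AT1G78995 and AT5G62280. For AT5G22460, AT2G14900 and AT5G18460, 1 of the 2 infested arrays was at or below the level of absent transcripts, and their folds of 7.20, 6.11 and 5.20 became 4.34, 3.63 and 3.45 with a pseudocount of 64. With a pseudocount of 1 AT2G14900 was below the filter. Which genes rank among the 12 depends on the scale and the fit: 11 of the rises and 9 of the falls were among the 12 with a pseudocount of 1, 10 and 10 with 64, 8 and 6 with the replicate experiment as a block, and 1 and 2 without infested 1. All 24 genes had an adjusted p of at most 0.0499, and with a pseudocount of 1 AT2G44240, EXPB1 and AT5G18460 lost their calls (adjusted p = 0.0511, 0.0501 and 0.0568).

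**Figure D1:**
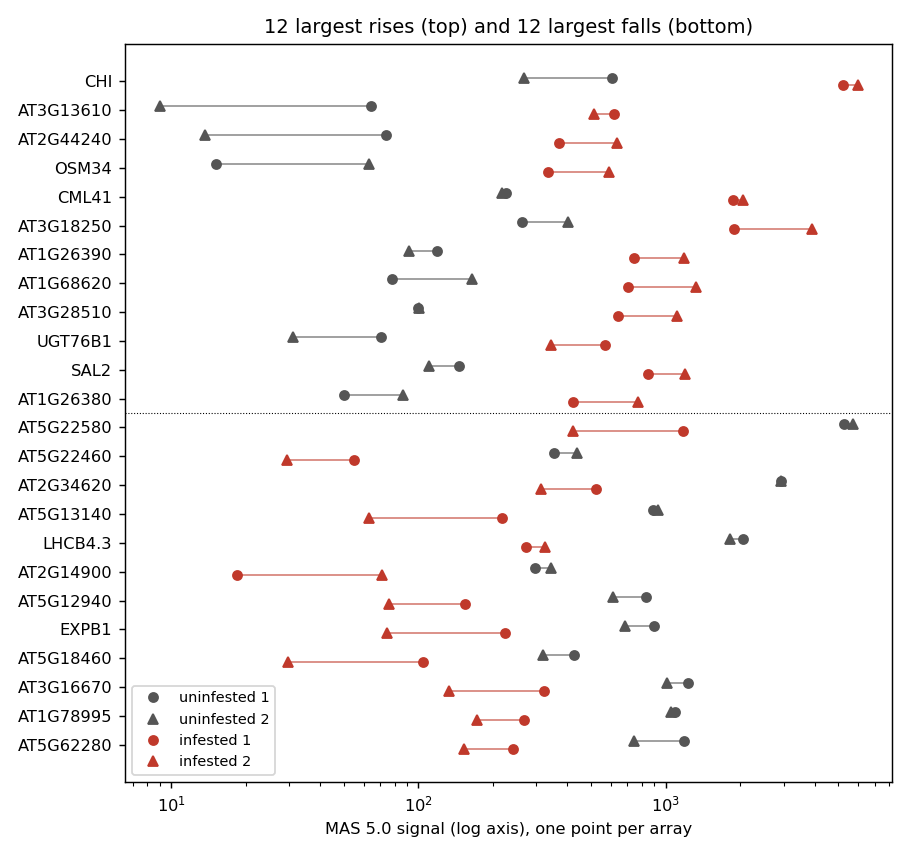
Signal of the 12 largest named rises (top) and the 12 largest named falls (bottom) on each array, on a log axis, with circles for replicate 1 and triangles for replicate 2 of the uninfested (grey) and infested (red) groups, joined by a line within each group. Within each of the 24 genes, which were chosen for their change, the arrays of one group lie apart from those of the other, as for CML41, at 226.4 and 216.9 against 1865 and 2048.

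Of 13648 probe sets tested, 386 were higher and 347 lower in infested leaves, 733 in all or 5.37%, and the median log2 change of those called was 1.45 and -1.31. Of the 386 higher ones 199 were unnamed here, and of the 347 lower ones 159. The largest called rise was log2 4.76, against 3.73 for CHI, the largest among called probe sets with 1 gene. Which direction had more calls turned with the scaling, to 335 higher and 526 lower with median scaling and to 349 and 360 with quantile normalization. Of those called, 311 of the 386 and 305 of the 347 changed more in the second pair of same-numbered arrays than in the first. Without any test, 268 probe sets were at least 2-fold higher and 221 at least 2-fold lower in all 4 ratios of an infested to an uninfested array. Taking the replicate experiment as a block raised the calls to 1254 and 1403, with all 733 among them. The calls rest on the filter and on single arrays: with every probe set tested, limma called 0 higher and 0 lower (2453 and 2203 at an unadjusted p under 0.05), without uninfested 1 it called 0 and 0 (827 and 804), and without uninfested 2 again 0 and 0 (978 and 948). Without infested 1 the counts were 2065 and 2487, and without infested 2 they were 638 and 690. The 2-fold counts became 728 and 1082 without infested 1, and the lower one 368 without uninfested 2. Fewer ratios must pass when an array is left out, so these 2-fold counts could only rise or stay the same. The limma fits without an array take their spread from the other group alone. Its log2 differences had an SD of 0.280 (uninfested) or 0.526 (infested). The number of calls thus depends on that spread, and a count of 0 does not show that 1 array carried the changes.

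**Figure D2:**
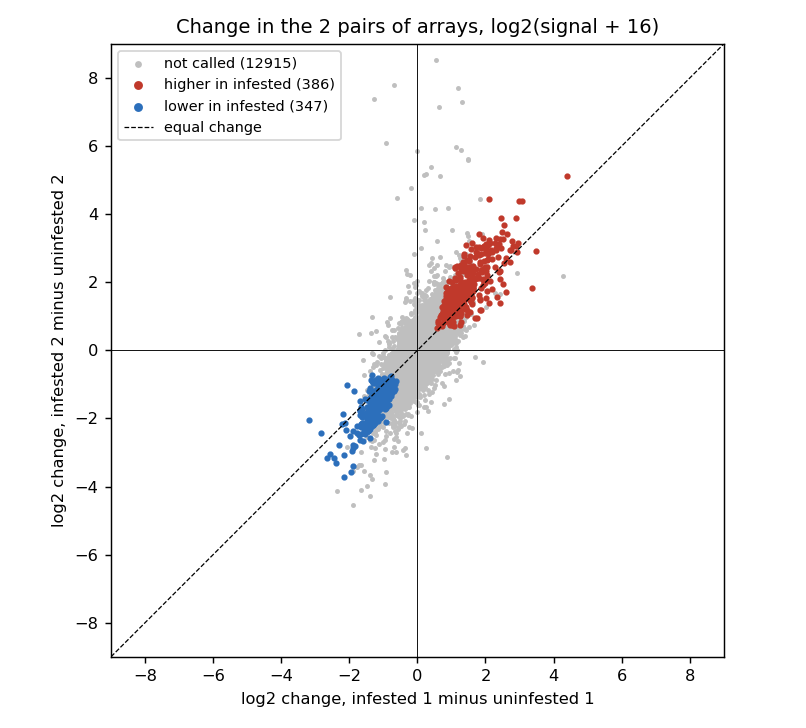
Log2 change of each of the 13648 tested probe sets in the first pair of arrays (horizontal axis) and in the second (vertical axis), on log2(signal + 16), with probe sets higher in infested leaves in red, lower ones in blue and the others in grey. Most coloured points lie farther from 0 on the vertical axis than on the horizontal one, as 311 of the 386 red and 305 of the 347 blue points do, and a group of grey points stands high on the vertical axis alone.

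Hormone pathways could be followed through few named genes. Of the salicylic acid list, 2 of 28 genes were tested and both rose: SAG101, which acts with EDS1 in resistance signalling, from 193.2 ± 3.04 to 422.3 ± 19.7 (SD, n = 2), and GRX480, a glutaredoxin gene induced by salicylic acid, from 293.3 ± 1.27 to 1273 ± 693. Their adjusted p was 0.0378 and 0.0488, and both also passed when adjusted over the list alone. GRX480 lost its call with quantile normalization (adjusted p = 0.0517) and with median scaling (0.0536). The single tested gene of jasmonate synthesis, OPCL1, had signals of 1885 ± 72.7 and 1800 ± 139, a difference within the replicate spread (adjusted p = 0.814). In the ethylene and ethylene-jasmonate defence list, 3 of 23 genes were tested and 0 passed by limma over all probe sets, while 2 passed adjusted over the list alone. The defensin gene PDF1.2 had 779.9 ± 111 in uninfested and 404.3 ± 68.5 in infested leaves (log2 change -0.92, adjusted p = 0.0589, or 0.00999 with the replicate block). Its near-identical paralog PDF1.2b had a log2 change of -0.93 (adjusted p = 0.0743, or 0.00845 with the block), and the probes may not tell these copies apart, while EIN3 had 0.47. The list as a whole did not pass (median -0.92, camera adjusted p = 0.236).

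Of 7 fixed lists tested, photosynthesis alone was called. All 7 of its tested genes, of 33 listed, were lower in infested leaves by value, with a median log2 change of -0.58. Of these, 2 passed the test: LHCB4.3 and SBPASE, a Calvin cycle phosphatase gene, from 13921 ± 105 to 6256 ± 1617 (SD, n = 2). A total of 6 passed when adjusted over the list alone, and 4 over all probe sets with the block. PRK, the phosphoribulokinase gene, had a log2 change of -0.72 (adjusted p = 0.0807, 0.0237 with the block), LHCB4.2 had -0.58 (0.0613, 0.0327 with the block), and RCA, for Rubisco activase, had -0.16. The list was lower than other genes by camera with a preset correlation (adjusted p = 0.000108), but not with an estimated correlation (adjusted p = 0.523), a form with little power here. Quantile normalization left the call in place and brought the median to -0.31, and SBPASE lost its own call there (adjusted p = 0.0565), while median scaling added LHCB4.2 (adjusted p = 0.0435).

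Genes grouped by a shared word in their annotation names, a grouping made after the data were examined, gave 5 lower and 0 higher groups among 83 by camera, and 0 with an estimated correlation (adjusted p = 0.840 for each). In the chlororespiratory group, whose genes serve the chloroplast NADH dehydrogenase-like complex, 2 of 5 fell: NdhL (log2 change -1.58 ± 0.17, SE) and CRR42 (-0.95 ± 0.18), and the group median was -0.95 (adjusted p = 0.00361); with the block 4 passed. In the thylakoid group 2 of 5 fell, TROL (-1.33) and AT1G52220 (-1.48), which is CURT1C of the proteins that bend thylakoid membranes, and the median was -0.75 (adjusted p = 0.0218); with the block 3 passed. The photosystem group (5 genes, median -0.58, adjusted p = 0.00361) shared the LHCB4 genes with the fixed list, and LHCB4.3 was its only gene past the test without the block, against 3 with it. The word "complex" joined 13 genes of unlike function, of which 4 fell: LHCB4.3, NdhN, NdhL and CCB3, the last needed to build the cytochrome b6f complex (adjusted p = 0.00644), and 6 passed with the block. Of 9 expansin genes, EXPB1 and EXPA4 fell, or 6 with the block, and the median was -1.02 (adjusted p = 0.0415), with positive values for EXPA9 (0.62) and EXLA1 (0.40). Without infested 1 there were 9 lower and 2 higher groups, without uninfested 1 there were 5 and 1, the block gave 8 and 0, and a filter at the 60th percentile gave 3 and 0 among 49. The expansin group lost its call with median scaling (adjusted p = 0.0705), with that filter (0.0756) and without infested 2 (0.0637).

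**Figure D3:**
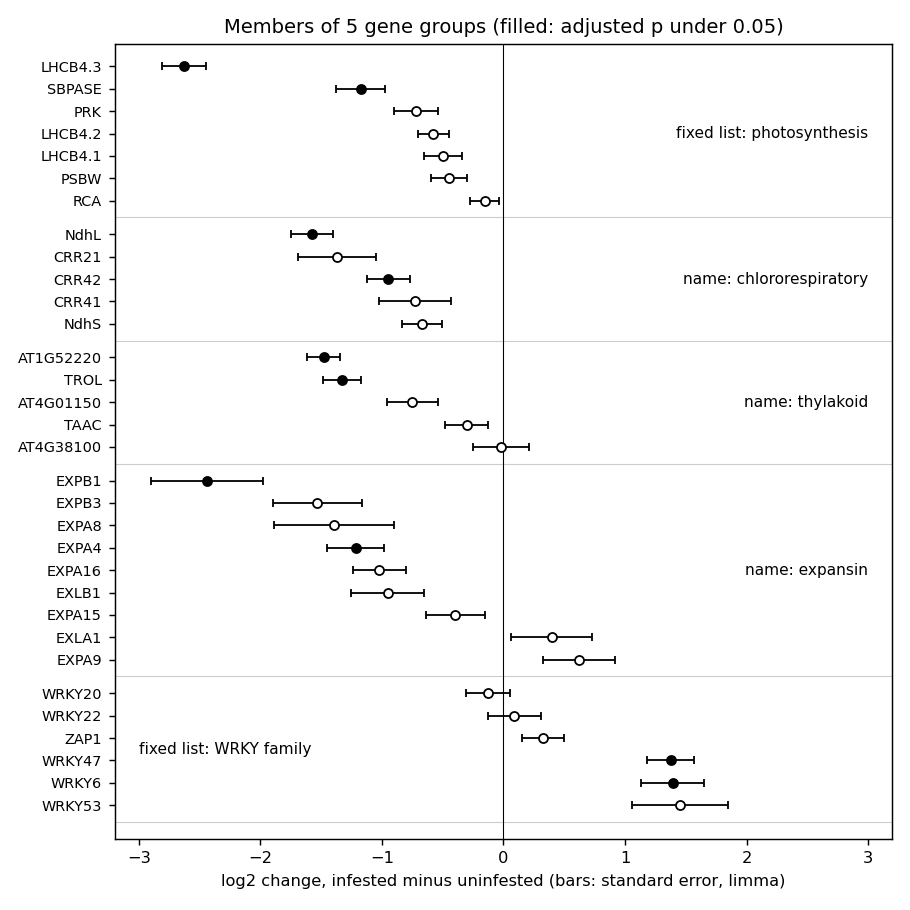
Log2 change, infested minus uninfested, of the tested members of 5 gene groups, with bars for the standard error from limma and filled points for adjusted p under 0.05. All 7 photosynthesis genes lie left of 0, from LHCB4.3 at -2.63 to RCA at -0.16, whereas WRKY6 and WRKY47 lie right of 0 at 1.39 and 1.38.

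Among 6 tested genes of the WRKY family of transcription factors, 2 rose, or 3 with the block: WRKY6, linked to senescence and defence, from 91.1 ± 7.35 to 270.7 ± 81.8 (SD, n = 2), and WRKY47, from 233.5 ± 34.0 to 631.1 ± 84.1. WRKY6 lost its call with quantile normalization (1.36, adjusted p = 0.0536). WRKY53 had a log2 change of 1.45 (adjusted p = 0.0919, 0.00243 with the block), and ZAP1 had 0.32. The family median was 0.85, with a camera adjusted p of 0.0552, of 0.0227 with the block and of 0.523 with an estimated correlation. The family passed without uninfested 1 (0.73, adjusted p = 0.0463), without uninfested 2 (0.91, 0.0183) and without infested 1 (0.98, 0.0489), and not without infested 2 (0.56, 0.0756); with every probe set tested its median was 0.32 over 7 genes (adjusted p = 0.0298). The leaf senescence list held 3 tested genes, all of them WRKY genes, of which WRKY6 rose, or 2 with the block (median 1.39, adjusted p = 0.104, or 0.0352 with the block), with WRKY22 at 0.09. With an estimated correlation its adjusted p was 0.523. It passed with every probe set tested (1.42, adjusted p = 0.0298), without uninfested 2 (1.46, 0.0331) and without infested 1 (1.69, 0.0491). Of the abscisic acid, cold and dehydration list 0 of 4 tested genes passed by limma, with 2 passing over the list alone and 2 with the block. LTI30 had a log2 change of 1.04 (adjusted p = 0.117, 0.00664 with the block), COR47 had 0.94 (0.0536, 0.00954 with the block), COR15A had 0.27 and COR15B -0.38, and the list median was 0.60 (camera adjusted p = 0.192, or 0.523 with an estimated correlation), or 0.76 without uninfested 1 (adjusted p = 0.00773). The sugar transport list had 0 of 3 past the test (median 0.09, adjusted p = 0.304), where SWEET11, a sucrose exporter gene, had 1.13 (adjusted p = 0.0553, 0.00423 with the block), APL3 had 0.09 and SWEET4 had 0.03, or -0.02 with median scaling. The 3 tested reference genes lay at 0.31 (AT4G34270), 0.24 (PEX4) and -0.13 (AT2G28390), with 0 past the test.

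Of the lists of cell type markers, guard cells alone had tested members. AT1G22690, a gene used as the guard cell marker GC1, fell from 1776 ± 91.6 to 895.9 ± 59.0 (SD, n = 2; limma adjusted p = 0.0411), and FMA, a regulator of guard cell identity, had 268.5 ± 21.3 and 210.0 ± 65.2. Of the cell wall list, XTH16 and EXPA8 were tested, each with a log2 change of -1.40 and an adjusted p of 0.0740 and 0.142 (0.00699 and 0.00836 with the block). In the glucosinolate lists UGT74B1 had 0.07, BCAT4 had -0.29 and AT2G31790 had -0.89 (adjusted p = 0.115, 0.0213 with the block), and the clock gene GI had 0.32. The ratio of 3' to 5' signal is a sign of RNA integrity, and the control probe sets differed on it. It was 2.70 and 3.88 on the uninfested and 5.70 and 6.56 on the infested arrays for one pair of actin probe sets, and 1.43 and 1.42 against 1.31 and 1.43 for another. For one GAPDH pair it was 1.17 and 1.15 against 0.975 and 1.02, and for one ubiquitin pair 2.77 and 2.34 against 2.08 and 1.87. A second GAPDH pair went the other way, at 1.09 and 0.980 against 1.14 and 1.17. A second ubiquitin pair had 1.64 and 1.74 against 1.45 and 1.31. These values go with all of the groups above.

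The array infested 2 stood apart from the other 3. On it, 26 probe sets were at least 8-fold above the highest of the other arrays and 8 were at least 8-fold below the lowest, against 0 and 0 on each of the other 3 arrays. These genes were chosen after their values were seen. They included small heat shock protein genes, such as ATHSP22.0 with 3758 on infested 2 against 163.4 on infested 1 and 141.1 and 90.8 on the uninfested arrays, and AT2G29500 with 7834 against 198.8, 82.1 and 108.7. The co-chaperone genes Hop3 (2882 against 63.7 on infested 1) and Fes1A (5253 against 467.8) were among them too. None of the 26 was called without the block, and the limma adjusted p of the 12 named ones ran from 0.150 to 0.436. With the block, AT1G53540 (11210 on infested 2 against 124.5 on infested 1) was called. It then had the largest rise among called probe sets with 1 gene. A signal that is far higher on infested 2 alone can thus pass the blocked fit. The blocked results of the others among the 26 are not given here.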

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

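The tests of the 25S signal, of the spiked-in controls and of the slopes between pairs were chosen after the results they bear on were seen; for the tests against matched lists, the medians had been seen and the percentiles had not.

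The control probe set for 25S ribosomal RNA, which no comparison uses, was 2.01 times as high in infested as in uninfested leaves, with 94.6 and 133.8 on the uninfested and 156.9 and 302.8 on the infested arrays. The 5S probe set read 78.3 and 49.3 against 77.0 and 36.2.

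Transcripts of the mitochondrial genome were higher in infested leaves by value, with a median log2 change of 0.75 over 7 genes, 0 of them past limma's test (adjusted p from 0.0747 to 0.460) and 6 with the replicate block. The set was called by camera (adjusted p = 0.000508), but not with an estimated correlation (adjusted p = 0.348). RNA without a poly(A) tail entering the labelling, which the 25S signal could track, predicts median differences of 0.765 between the infested and 0.379 between the uninfested arrays; the observed ones were 0.223 (SE 0.182, allowing for correlated genes) and 0.218 (SE 0.154). The first lies more than 2 standard errors below its prediction and the second less than 2, and both lie within 2 standard errors of 0. The prediction is scaled from the change of these same genes between the groups and gives the 25S probe set no error. The comparison thus cannot decide, and this explanation stays open. The median lay at the 99.95th percentile of 10000 random lists of matched signal, above what a shift of all dim probe sets gave there. Those lists draw genes independently, while these genes had an estimated correlation of 0.332, so the percentile cannot exclude such a shift. A response of the leaf, and probes that also read nuclear copies of mitochondrial DNA, stay open and untested.

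The photosynthesis genes, lower by a median of -0.58, could follow a fall of all bright probe sets. Matched lists had a median of -0.14 and a lowest 2.5% below -0.45, and the photosynthesis list lay at percentile 1.13. The pool for these lists left out only the list's own genes, so it kept plastid-encoded genes and other photosystem genes, which may share the fall. The lists thus cannot tell a shift of all bright probe sets from a fall of photosynthesis genes. A shift of bright probe sets may account for part of the value, but its share was not measured. The matched lists draw genes independently, while the photosynthesis genes had an estimated correlation of 0.365. The percentile thus cannot settle whether such a shift accounts for all of the value. Quantile normalization, which gives all arrays the same distribution, left a median of -0.31. The median was -0.41 in the first pair of arrays and -0.75 in the second, which holds infested 2. A response to infestation stays open as a hypothesis. RNA integrity, on which the control probe sets differ, was not tested, nor was the condition of the infested 2 pool in which heat shock genes were high.

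Changes were larger in the second pair, with a slope of 1.17 (SE 0.0086 across probe sets, which are not independent) for its log2 changes on those of the first. Noise on infested 2 would not raise the slope above 1, and the slope with the pairs crossed was 1.07. A wider signal scale on infested 2 that arose at hybridization is argued against by the 18 spiked-in control probe sets. Their slope between the infested arrays was 0.984 (SE 0.0147). These are hybridization controls, so they cannot show whether the scale widened in the RNA or its labelling. The 26 probe sets that stood far higher on infested 2 alone do not carry it, since the slope without them was still 1.17 (SE 0.00768). A stronger infestation, or another condition of that pool such as the one in which the heat shock genes were high, may differ between the experiments, and neither was tested.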

How the results depend on the processing

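The family test by cameraPR and the groups by annotation name and by genome were chosen after the data were seen. No named gene or fixed list that was called changed direction. The balance of the calls did turn: 52.7% of them were higher, against 38.9% with median scaling, which gave 526 lower calls, 49.2% with quantile normalization, 47.8% with a filter at the 60th percentile, 47.2% with the replicate block, 45.4% without infested 1 and 48.0% without infested 2. With no filter there were 0 higher and 0 lower calls over 22746 probe sets, and the WRKY median was 0.32 (adjusted p = 0.0298). A filter at the 60th percentile left 165 probe sets at least 2-fold higher. The replicate block gave 1254 higher and 1403 lower calls, 352 probe sets at least 2-fold lower in both pairs and a WRKY median of 0.85 (adjusted p = 0.0227); besides the calls given in the report it raised the name groups that were lower from 5 to 8 and changed no other list, while a filter at the 60th percentile left 3 lower of 49. No variance trend gave 199 lower calls, and an adjusted p under 0.10 gave 980 and 968. The photosynthesis median of -0.58 lost its call with an estimated correlation (adjusted p = 0.523) and with fry (0.120). The cause of these changes was not tested. Without single arrays, higher calls ranged from 0 to 2065, lower calls from 0 to 2487, probe sets at least 2-fold higher from 298 to 728, those lower from 241 to 1082, and the WRKY median from 0.56 to 0.98. In these fits the lone array is assumed to vary like the other group, whose log2 differences had an SD of 0.280 (uninfested) or 0.526 (infested). The 2-fold counts in both pairs or without an array rest on fewer ratios, so they could only rise or stay the same. The leaf senescence and abscisic acid lists crossed the threshold only where the report says so, and the ethylene, sugar and reference lists never did. Of the 30 named genes that were called, 26 of 29 stayed with a pseudocount of 1, 27 with quantile normalization and 29 with median scaling, and none without filter or without either uninfested array. In the form of the family test looked at first, cameraPR with organelle genes included, 9 name groups of 100 were lower and 4 higher. The higher ones were calmodulin and WRKY genes under 2 names each. Among the lower ones, the chlororespiratory and the expansin genes also stood under 2 names each. The filter left out 9098 probe sets. Signal over background limits 3891 of them, at or below the bacterial controls on every array, and 2861 in part, while 2346 were above the controls on every array and were left out by the filter alone.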

Other observations

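The genes described next were chosen after their values were seen. Glutamate receptor-like genes, which encode ion channels of wound signalling and defence, included 3 of 6 tested members that rose: GLR2.8 (log2 change 1.57 ± 0.26, SE), GLR2.7 (1.42 ± 0.26) and GLR1.4 (1.22 ± 0.21), while GLR3.6 (-0.16), GLR3.5 (-0.27) and GLR3.3 (0.12) did not pass the test. As a group they were not called by camera (adjusted p = 0.181). The receptor-like cytoplasmic kinase gene BIK1, a hub of immune signalling, rose by 1.17 ± 0.19. The subtilase genes SBT3.3 and SBT3.5 rose by 2.55 ± 0.37 and 2.07 ± 0.24. The alpha-amylase gene AMY1 rose by 2.65 ± 0.26, the sugar exporter gene SWEET13 by 0.99 ± 0.19 and the cell wall invertase-like gene cwINV6 by 1.69 ± 0.31. Each of these rises had a limma adjusted p of at most 0.0477. Of 7 tested SWEET genes 1 passed and 4 had negative values. Their median was -0.01, and camera did not call them as a group (adjusted p = 0.712).

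Single genes that fell, picked by their values and not tested as a group, were CHLI2 (-1.80 ± 0.33, SE), CHLM (-1.22 ± 0.19) and HEME2 (-1.31 ± 0.23), which encode enzymes of tetrapyrrole synthesis, and PSB27 (-1.18 ± 0.17), LPA2 (-1.11 ± 0.16) and PAM68 (-1.38 ± 0.23), whose products act in photosystem II assembly. The cytokinin-induced response regulator genes RR16 and ARR15 had log2 changes of -2.02 ± 0.17 and -1.64 ± 0.26. STOMAGEN, whose peptide promotes stomata and is made in the mesophyll, had -1.75 ± 0.29. All had a limma adjusted p of at most 0.0452.

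Of 68 genes of the plastid genome, 54 had negative and 14 positive values, with a median log2 change of -0.16; rpl36 alone passed the test (-1.02) and is named for that, while 11 lower and 1 higher passed with the replicate block. The set was called by camera (adjusted p = 0.000142), but not with an estimated correlation (adjusted p = 0.375), nor after quantile normalization (median -0.08, adjusted p = 0.131), nor without uninfested 1 (median -0.07, adjusted p = 0.136). Its median lay at percentile 10.15 of lists matched on signal, whose pool kept the nuclear photosynthesis genes.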
